A study of Mus musculus with 11 samples.

How the data were processed

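Whole hearts of male mice aged 8 to 12 weeks were measured by RNA sequencing of polyA RNA, 1 library per sample, in 11 libraries of 4 groups, each library placed by its own labels. In the Macrophage-depleted group (n = 3), mice carried the diphtheria toxin receptor under control of the CD169 locus (CD169-DTR) and received toxin for 3 weeks at 0.01 µg per g of body weight, with macrophages depleted for 21 days. WT mice (n = 3) received the same toxin injections. The Mertk-KO group (n = 2) is labelled as lacking the phagocytic receptor Mertk and the LXR-DKO group (n = 3) as lacking both liver X receptors, alpha and beta. The labels do not say whether these 2 groups received toxin, nor at what time of day hearts were collected. Nothing in the labels says that each library came from a separate mouse, so the p-values measure only the spread between these libraries, which may be partly technical.

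Per the labels' protocols, RNA was extracted with Trizol, amplified with a single-cell kit (Ovation, NuGen) and made into Illumina libraries. The submitters' processing notes name CASAVA 1.8.2, cutadapt (no version), RSEM 1.2.20, kallisto 0.43.1 and the GRCm38 genome, without a role for each. Which tool made which table, the scaling method, the annotation release and whether strand was used are not given in the sources used here. The authors deposited 2 tables that hold all 11 libraries, and no column was left unassigned. The values of the first table are a signal per gene, deposited by the authors as a normalised count: reads on a per-million scale of an effective library size, with 0.5 read added to every gene, as read from the values themselves. The values of the second table are a signal as well, deposited as normalised TPM (the transcript-per-million measure) and rescaled between libraries, since its columns do not share 1 sum. The first table held 35584 genes and the second 33318, of which 22331 were shared. The 13253 genes of the first table alone included 3490 lincRNAs, and the 10987 of the second alone included 7247 processed pseudogenes.

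In each library the smallest value of the first table is worth 0.5 read, so the added part was removed and estimated reads were recovered. Between 58.8% and 62.0% of the low values were whole within 0.01 read, so these are estimated reads and not whole counts, and no test that models whole counts was run. Voom, which takes its weights from the estimated reads, was run only as an alternative chosen after seeing the data. Totals ranged from 10938600 to 20722295 estimated reads. Estimated reads were divided by each library's effective size and multiplied by the mean effective size of the libraries, and the result is called the normalised count. A gene with 0 reads in a library can have up to 3 reads' worth, or 2.12 to 4.22 normalised counts depending on the library, and this floor covers counting error only, since amplified reads without molecular identifiers are not independent molecules. The minimum and the pseudocount fixed before the data were examined had been written for normalised counts and were applied on this scale of reads, where a mean of 10 is worth 0.650 on the deposited per-million scale. The per-million version was run as an alternative chosen after seeing the data.

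Genes with a mean of at least 10 normalised counts over the 11 libraries were tested, 13884 in all. The test was limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes with a trend) on log2(normalised count + 1), with 1 model for the 4 groups and 7 residual degrees of freedom, two-sided, and Benjamini-Hochberg adjustment with a threshold of 0.05 over the genes of each comparison. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. All 6 comparisons between groups were made. Mertk-KO and LXR-DKO were each set against WT although toxin treatment may differ, so that genotype and toxin cannot be separated there. Macrophage-depleted mice differed from WT in the CD169-DTR allele as well as in depletion, and these cannot be separated either. Same-numbered libraries were not treated as pairs, since the labels tie no numbers together. Values are given as mean ± SD; SE is that of the fold change.

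Genes were named by a rule fixed before the data were examined: the targeted genes Siglec1 (which encodes CD169), Mertk, Nr1h3 and Nr1h2 (which encode the liver X receptors); for each comparison with WT, the 8 higher and the 8 lower genes with the greatest fold change among those past the threshold whose libraries did not overlap between groups, leaving out predicted gene models; and up to 4 members with the smallest p of each gene list. For the 3 direct comparisons between perturbed groups the rule took 4 in each direction. Members of a list that passed the threshold within it are also named as examples, and genes named for another reason are said to be chosen after their values were seen. The 38 gene lists, of cell types of the heart, pathways and stress responses, were also fixed before the data were examined. Each list was tested with camera in limma with a preset inter-gene correlation of 0.01, adjusted over the 38 lists of a comparison, and its members were counted both over all genes tested and adjusted over the list alone. Several lists share members. Camera with an estimated correlation and fry were alternatives.

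Gene positions and types came from the GENCODE M21 annotation of GRCm38, matched by gene identifier; a symbol was found for 35469 identifiers of the first table and 32861 of the second. Transcript length and GC content were known for 13871 of the tested genes. For the positions of called genes, each chromosome was tested with Fisher's exact test, one-sided. For similarity between comparisons that share the WT libraries, 100 sets of unchanged groups were simulated against the same WT libraries. The statistics were tested on simulated data with 200 changed genes among 13884 in each comparison. For Macrophage-depleted against WT, 46.3%, 68.7% and 92.4% of genes changed 1.5-fold, 2-fold and 4-fold were found, and 4.17% of calls were false. For Mertk-KO against WT these shares were 40.3%, 80.6% and 83.3%, with 8.11% false, and for LXR-DKO against WT 53.7%, 80.6% and 93.9%, with 5.0% false. Simulated genes were independent, had the same spread in every group and carried no trend with transcript length. The Mertk-KO libraries differed more from each other and ran with transcript length, so the simulated shares do not carry over to their calls.

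Alternatives planned beforehand were pseudocounts of 0.5 and 5, no minimum, a minimum of 50, the TPM table (log2(TPM + 0.5), mean of at least 1), median-of-ratios and quantile scaling, eBayes without trend, robust eBayes, weights per library, a fit of only the groups compared, the replicate number as a block, a threshold of 0.1 and leaving out each library in turn. Added after seeing the data were voom on estimated reads, the per-million scale, removal of each library's trend with transcript length and GC, and a fit without the Mertk-KO libraries. The transgene for the toxin receptor was not analysed here. Figures were drawn with matplotlib 3.10.9.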

Results

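Heart RNA was compared between mice labelled as depleted of CD169-expressing macrophages (Macrophage-depleted, n = 3), mice labelled as lacking the phagocytic receptor Mertk (Mertk-KO, n = 2), mice without both liver X receptors (LXR-DKO, n = 3) and toxin-treated wild-type mice (WT, n = 3). The WT libraries held 14295229, 14860043 and 14606872 estimated reads and the Macrophage-depleted libraries 10938600, 20517786 and 20722295. The Mertk-KO libraries held 11794185 and 15368030, and the LXR-DKO libraries 16534157, 12658550 and 16378116. Between 17460 and 19903 genes had at least 1 read in a library. Transcripts encoded by the mitochondrial genome took 31.4% to 36.5% of the reads, and the 10 most abundant genes of each library took 31.4% to 35.3%. Across genes, the log values of replicates correlated at 0.959 for the Mertk-KO pair, the lowest value, and up to 0.987 within the other groups. No pair of replicates was as close as sampling of reads alone would give: the median chi-square per gene was 0.862 to 3.25, against 0.455 for sampling only.

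The targeted genes were examined first in every library. Siglec1, which encodes CD169 (ENSMUSG00000027322; GRCm38 chromosome 2, 131069220 to 131086765), had 64.3, 55.3 and 53.4 normalised counts in the WT libraries. In the Macrophage-depleted libraries it had 33.8, 2.12 and 0.719, so that Macrophage-depleted 1 kept more of it than the other 2, and the group difference did not pass the threshold (log2 fold change -3.36, SE 0.80, limma adjusted p 0.178). Without Macrophage-depleted 1 the difference was -4.66 with an adjusted p of 0.000159, in a range of 0.000159 to 0.544 over its 25 alternatives. In the Mertk-KO libraries Siglec1 was at 87.9 and 66.8, and in the LXR-DKO libraries at 63.5, 46.9 and 47.1. The toxin receptor is under control of the same locus, so Siglec1 alone cannot tell loss of cells from an effect of the CD169-DTR allele.

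Mertk (ENSMUSG00000014361; chromosome 2, 128698956 to 128802894) had 131, 147 and 130 normalised counts in WT and 75.7 and 89.4 in the libraries labelled Mertk-KO. It fell by 0.71 on the log2 scale (SE 0.19, limma adjusted p 0.0408), to 60.7% of the WT mean. The call was lost without WT 1 (adjusted p 0.0883), WT 2 (0.120), WT 3 (0.0931), Macrophage-depleted 2 (0.0527), Mertk-KO 1 (0.121) or LXR-DKO 1 (0.0611), in a range of 0.0283 to 0.232 over its 26 alternatives. Mertk was also at 72.1% of WT in Macrophage-depleted and 72.8% in LXR-DKO, without passing the threshold. A value over the whole gene cannot show which part of a transcript a targeted allele lacks, and that part is not given in the sources used here, so Mertk does not check these labels. Nr1h3, which encodes liver X receptor alpha (ENSMUSG00000002108; chromosome 2, 91184061 to 91202834), was at 27.7 ± 1.59 normalised counts (SD, n = 3) in LXR-DKO and 162 ± 9.87 (n = 3) in WT, with a log2 fold change of -2.50 (SE 0.12, adjusted p 6.01e-07). Nr1h2, which encodes liver X receptor beta (ENSMUSG00000060601; chromosome 7, 44549616 to 44553951), was at 92.2 ± 7.19 in LXR-DKO and 531 ± 10.5 in WT (-2.52, SE 0.09, adjusted p 3.25e-08). Both were lower in 3 of 3 LXR-DKO libraries than in every library of the other groups. In the TPM table the differences were smaller, -0.52 for Nr1h3 (adjusted p 0.329) and -0.74 for Nr1h2 (adjusted p 0.0143). The adjusted p ranged from 7.84e-09 to 0.329 over 27 alternatives for Nr1h3 and from 1.97e-10 to 0.0143 over 28 for Nr1h2.

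**Figure D1:**
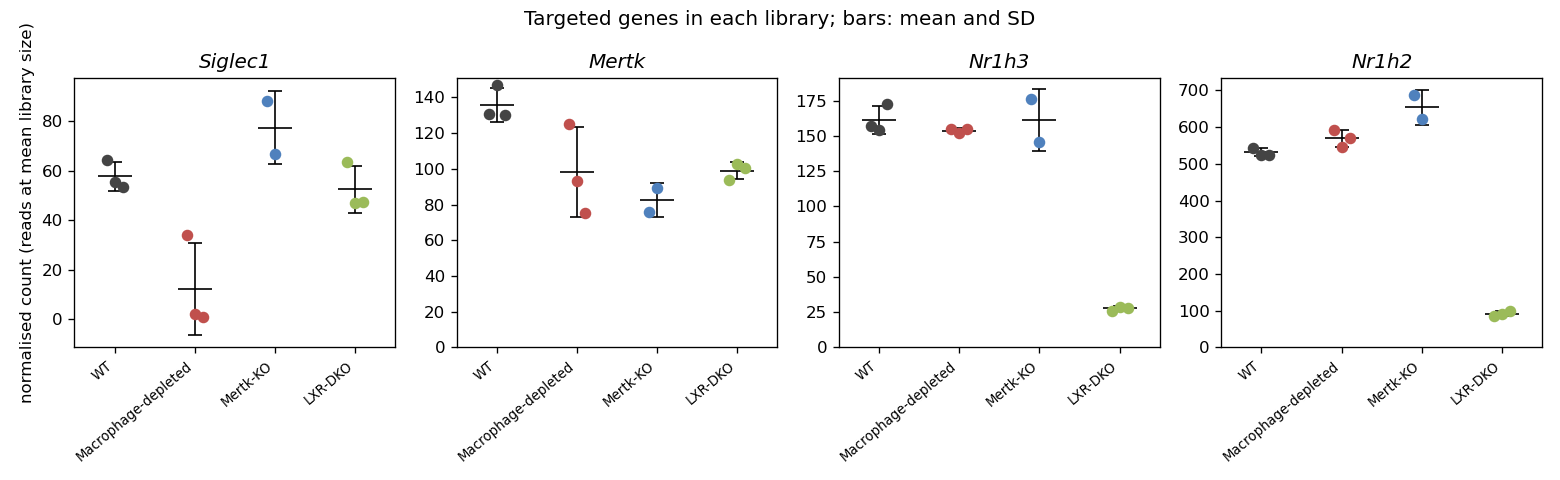
Normalised counts of Siglec1, Mertk, Nr1h3 and Nr1h2 in each of the 11 libraries, with 1 panel per gene and group means ± SD. Siglec1 is at 33.8, 2.12 and 0.719 in the Macrophage-depleted libraries against 53.4 to 64.3 in WT, and Nr1h2 is at 85.2 to 99.6 in LXR-DKO against 525 to 543 in WT.

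The comparison of Macrophage-depleted with WT asks what loss of CD169-expressing macrophages does to heart RNA. Among the genes named by the rule, which leaves out predicted gene models, Mmp13, Timd4 and Cd163 had the largest fitted falls. Timd4, a receptor for phosphatidylserine on resident macrophages, was at 1.66 ± 0.403 normalised counts (SD, n = 3) after depletion and 31.6 ± 6.18 (n = 3) in WT (log2 fold change -3.61, SE 0.37, adjusted p 0.00343). Cd163, the scavenger receptor for haemoglobin-haptoglobin complexes, was at 23.5 ± 14.5 against 223 ± 16.7 (-3.42, SE 0.39, adjusted p 0.00749), and lower in 3 of 3 depleted libraries. The collagenase gene Mmp13 had 2 estimated reads in the 3 depleted libraries together and 59 in WT, a ratio per read sequenced of 0.0284 (exact 95% interval 0.00336 to 0.107, counting error only), and its fitted log2 fold change of -3.76 (SE 0.59, adjusted p 0.0248) depends on the pseudocount. Lilra5, Pla2g2d, Chp2, Prnd and Apln (the ligand of the apelin receptor, 117 ± 25.9 against 274 ± 16.9) also fell, with log2 fold changes from -2.82 to -1.24.

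Among higher genes, Myh7, the slow myosin heavy chain, rose from 3587 ± 476 normalised counts in WT to 10911 ± 3161 in Macrophage-depleted hearts (log2 fold change 1.58, SE 0.19, adjusted p 0.00839). In the TPM table Myh7 was 0.81 higher on the log2 scale and did not pass (adjusted p 0.124, in a range of 0.000365 to 0.124 over its 28 alternatives). Capn3, Gchfr, Ppl, Gfpt2, Fmo2 and Ier3 rose by 0.73 to 1.25 on the log2 scale. Of these, Capn3 and Gchfr, on chromosome 2 as Siglec1 is, also rose in Mertk-KO and LXR-DKO against WT. Pcna-ps2, a processed pseudogene of Pcna on chromosome 19, was at 118 ± 56.4 against 2.96 ± 2.89, but it shares sequence with Pcna and its value is uncertain. In all, 33 of 13884 genes changed, 11 higher and 22 lower (limma, adjusted p below 0.05), and 1046 had an unadjusted p below 0.05. The count was 6 without WT 1, 15 without WT 2, 3 without WT 3, 16 without Macrophage-depleted 2, 9 without Macrophage-depleted 3, 84 without Mertk-KO 1 and 83 without Mertk-KO 2. It was 6 in the TPM table, 219 with weights per library and 66 when only the 2 groups were fitted. Of the 16 genes named by the rule, 4 passed without WT 1, 6 without WT 2, 2 without WT 3, 9 without Macrophage-depleted 2 and 5 without Macrophage-depleted 3. Timd4 and Pcna-ps2 passed whichever library was left out. Of the 12 that were tested in the TPM table, 4 passed: Pcna-ps2, Gchfr, Cd163 (at -2.46) and Apln.

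All 14 tested members of the resident cardiac macrophage list were lower in Macrophage-depleted hearts. Timd4 and Cd163 fell over all genes tested, and 11 members fell when adjusted over the list alone, among them Folr2 (42.2 ± 30.7 against 123 ± 17.5), Lyve1 (129 ± 32.4 against 208 ± 18.3) and Mrc1 (278 ± 177 against 470.0 ± 46.5). The list shifted down with a camera adjusted p of 4.98e-14, and with adjusted p = 0.232 with an estimated correlation. Its median difference from the WT mean was -0.42, -0.49 and -2.06 in Macrophage-depleted 1, 2 and 3. All 18 pan-macrophage genes were lower too, 0 of them past the threshold over all genes and 11 when adjusted over the list alone, among them Csf1r (307 ± 111 against 616 ± 37.0), Cx3cr1 and Lyz2 (camera adjusted p 4.15e-11; adjusted p = 0.518 with an estimated correlation). The 8 genes of monocytes and recruited macrophages lay in the other direction: all were higher, and Ccr2, the chemokine receptor of recruited monocytes, rose when adjusted over the list alone, from 63.5 ± 9.79 to 145 ± 34.1 (camera adjusted p 0.00865; adjusted p = 0.232 with an estimated correlation).

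Genes of other cell types and of the matrix moved in the same hearts. Of 8 adipocyte genes, 5 fell when adjusted over the list alone, among them Cfd (5.18 ± 3.15 against 38.1 ± 17.6) and Car3 (15.4 ± 2.71 against 58.7 ± 19.5), with a camera adjusted p of 3.6e-06 and adjusted p = 0.232 with an estimated correlation. The median of the adipocyte list was -1.07, -2.04 and -1.69 in Macrophage-depleted 1, 2 and 3. It ranged from -0.45 to 0.35 within WT and from 0.04 to 1.33 within LXR-DKO. Whether the amount of fat left on the hearts differed was not tested. Of 26 genes of extracellular matrix and fibrosis, Eln, which encodes elastin, fell over all genes tested (log2 fold change -0.96, adjusted p 0.0483), and 6 fell when adjusted over the list alone, among them Col4a1 and Sparc (camera adjusted p 1.7e-05; adjusted p = 0.546 with an estimated correlation). Of 18 circadian clock genes, 8 rose and 3 fell when adjusted over the list alone. Per1 (1394 ± 221 against 416 ± 177), Per2 and Ciart were higher and Arntl (18.2 ± 11.3 against 114 ± 74.2) was lower (camera adjusted p 0.0151; adjusted p = 0.518 with an estimated correlation). Of 19 LXR target genes, 17 were lower and Apoe, an apolipoprotein that macrophages make, fell (1437 ± 309 against 2750 ± 229; camera adjusted p 0.0238; adjusted p = 0.518 with an estimated correlation).

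Other lists that shifted in Macrophage-depleted hearts were those of erythrocyte genes (down, median -0.62, adjusted p 0.00483, 2 of 6 when adjusted over the list alone), B cell genes (down, 0.0456, 2 of 9) and endothelial genes (down, 0.0456, 1 of 14). The nuclear-encoded respiratory chain list was lower (0.00865, 0 of 50, median -0.06) and the lymphatic and mesothelial list higher (0.0290, 0 of 8, median 0.35). These 5 were lost with an estimated correlation, at adjusted p = 0.546, 0.572, 0.518, 0.815 and 0.518 with an estimated correlation, in that order. The B cell list was also lost without Macrophage-depleted 2 (0.108), Macrophage-depleted 3 (0.457), WT 2 (0.0775), WT 3 (0.110) or either Mertk-KO library (0.0710). The endothelial list was lost without Macrophage-depleted 1 (0.201), WT 1 (0.155) or either Mertk-KO library (0.0712), and the erythrocyte list without Macrophage-depleted 2 (0.0650). The respiratory chain list was lost and turned up without Macrophage-depleted 2 (0.917). The lymphatic and mesothelial list was lost without Macrophage-depleted 2 (0.127), WT 3 (0.160) or either Mertk-KO library (0.0567), and the LXR target list without Macrophage-depleted 3 (0.142) or WT 3 (0.0550). Complement genes went both ways: of 17, 7 were higher and 7 lower when adjusted over the list alone, with C3, C4b and Cfb higher and C1qa, C1qb and C1qc lower, a median of 0.27, a mean of -0.19 and a camera adjusted p of 0.879. Of the other lists, Hcn2, a pacemaker channel, fell (146 ± 19.1 against 296 ± 22.1, adjusted p 0.0171).

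**Figure D2:**
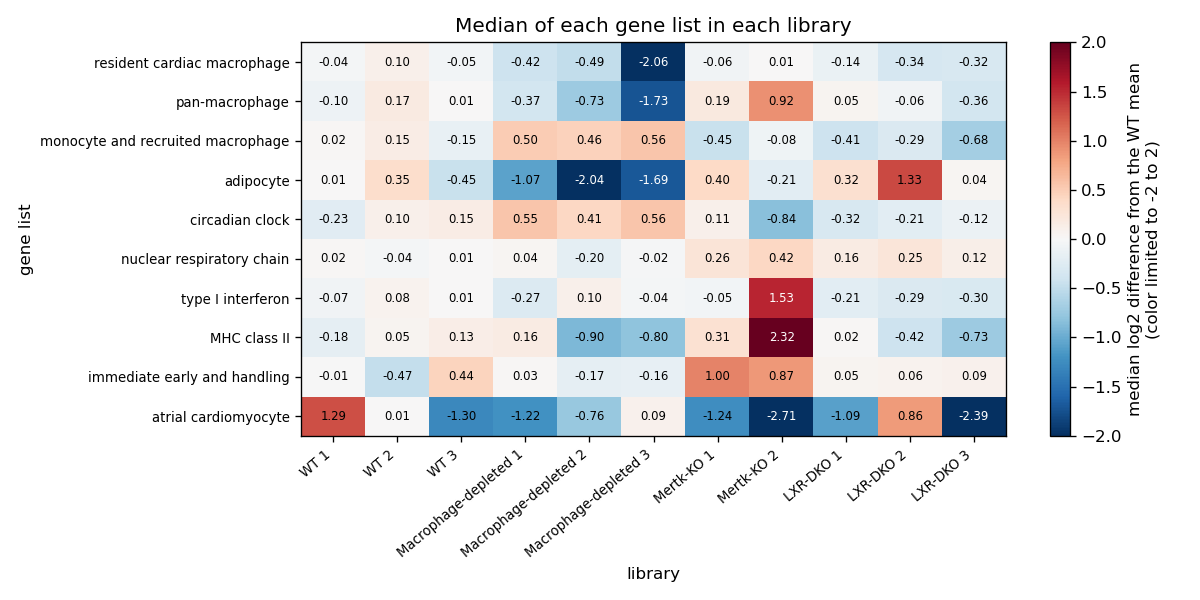
Median log2 difference from the WT mean over the tested members of 10 gene lists (vertical axis) in each of the 11 libraries (horizontal axis); color shows the printed value and is limited to -2 to 2. The resident cardiac macrophage list is at -0.42, -0.49 and -2.06 in the Macrophage-depleted libraries, and the MHC class II list is at 2.32 in Mertk-KO 2 and 0.31 in Mertk-KO 1.

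The comparison of the libraries labelled Mertk-KO with WT asks what loss of a receptor for the uptake of dying cells and debris does to heart RNA. Atf3, a transcription factor of the stress response, was at 255 ± 58.5 normalised counts (SD, n = 2) against 46.7 ± 29.4 (n = 3) in WT (log2 fold change 2.57, SE 0.39, adjusted p 0.00973). The heat shock genes Hspa1a and Hspa1b also rose (adjusted p 0.0329 and 0.0376), Hspa1a being at 2007 in Mertk-KO 1 and 105 in Mertk-KO 2 against 21.2 to 57.4 in WT. Nr4a1, the interferon-inducible Tgtp1, the Fc receptor gene Fcgr4 and Alx4 rose by 1.90 to 2.53 on the log2 scale. Rxfp1, the relaxin receptor, had 0 reads in both Mertk-KO libraries and 37.0 ± 23.1 normalised counts in WT, at least 20.7-fold lower against a floor of 3 reads over the group. Hamp, which encodes hepcidin, also had 0 reads there and was at least 17.2-fold lower by the same floor. Rxfp1 varied widely within other groups too, at 22.9 ± 20.9 in Macrophage-depleted and 32.8 ± 29.7 in LXR-DKO. The atrial gene Myl7 was at 203 and 22.6 in the Mertk-KO libraries against 505 to 3242 in WT. Whether a differing share of atrial tissue accounts for the falls of Rxfp1 and Hamp was not tested.

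Fgf12, Gdap10, Pla2g4b, Sorbs2os, Slitrk4 and Cenpf (132 ± 52.2 against 476 ± 123) fell in Mertk-KO hearts, with log2 fold changes from -4.01 to -1.86. Sorbs2os is antisense to another gene, and without knowledge of strand its reads cannot be told from those of its partner. Pcna-ps2 was higher as well (153 ± 17.2 against 2.96 ± 2.89), with the same uncertainty as above. In all, 1287 of 13884 genes changed, 469 higher and 818 lower, and 3977 had an unadjusted p below 0.05. The count was 164 without WT 1, 167 without WT 2, 70 without WT 3, 633 without LXR-DKO 1 and 2399 without Mertk-KO 2, where Mertk-KO 1 is alone in its group and is taken to vary as the other groups do. It was 12 with weights per library, 1 when only the 2 groups were fitted and 348 (231 higher, 117 lower, 181 shared with the 1287) after each library's trend with transcript length and GC was removed. Of the 16 genes named by the rule, Atf3 and Pcna-ps2 passed whichever library was left out; 5 passed without WT 1, 4 without WT 2, 5 without WT 3, 12 without Mertk-KO 1 and 10 without Mertk-KO 2. Pcna-ps2, Atf3 and Hamp were the 3 that passed among 9 tested in the TPM table, with Fgf12 at -1.80 in place of -4.01 and Cenpf at -0.68 in place of -1.86.

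In Mertk-KO hearts, of 50 nuclear-encoded respiratory chain genes 48 were higher, 21 rose over all genes tested and 36 rose when adjusted over the list alone. Ndufb8, a subunit of complex I, was at 6999 ± 365 against 5146 ± 331, and Cox4i1, of complex IV, at 18308 ± 393 against 13991 ± 682. The list had a median of 0.32 and a camera adjusted p of 8.03e-14, with adjusted p = 0.710 with an estimated correlation. Once each library's trend with transcript length and GC was removed, an alternative chosen after seeing the data, the median was 0.15 and 5 genes rose in place of 21 (camera adjusted p 8.60e-07). The mitochondrial-encoded list (13 genes, adjusted p 0.502) and the mitochondrial biogenesis and dynamics list (19 genes, adjusted p 0.609) did not pass. Of 21 glycolysis genes 10 rose, and 14 when adjusted over the list alone, among them Tpi1 and Pkm (camera adjusted p 7.68e-06; adjusted p = 0.530 with an estimated correlation). The fatty acid oxidation list (3 of 26 rose, 5 when adjusted over the list alone, adjusted p 0.0305) and the cardiomyocyte sarcomere list (3 of 17 rose; 8 rose and 1 fell when adjusted over the list alone, adjusted p 0.00905) were also higher, both with adjusted p = 0.741 with an estimated correlation. Among sarcomere genes Myl3 was higher and Ttn, which encodes titin and has a very long transcript, was lower. The fatty acid oxidation list was lost without Mertk-KO 1 (0.147), Mertk-KO 2 (0.0715) or WT 1 (0.110), and the sarcomere list without Mertk-KO 1 (0.196).

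Across genes, the difference of a library from the WT mean ran with transcript length, and genes are not independent replicates there. Spearman's rho was -0.255 and -0.50 in the Mertk-KO libraries, -0.250, -0.374 and -0.142 in the LXR-DKO libraries and -0.0365, 0.224 and 0.0604 in the Macrophage-depleted libraries. The median transcript length was 1306 bases for the respiratory chain list and 3381 for all genes tested.

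**Figure D3:**
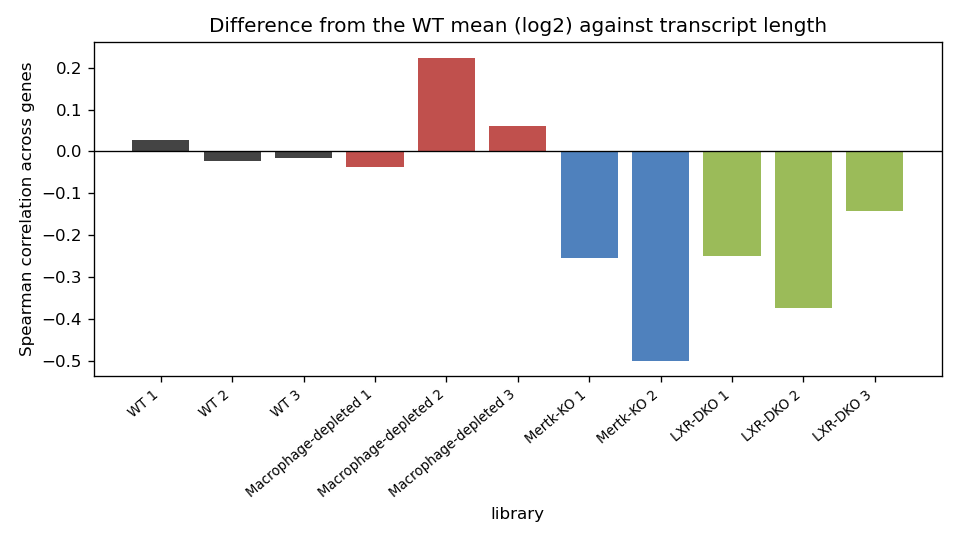
Spearman correlation across genes between each library's log2 difference from the WT mean and transcript length (vertical axis, no unit), with 1 bar for each of the 11 libraries (horizontal axis). Bars reach -0.255 and -0.50 in Mertk-KO, -0.250, -0.374 and -0.142 in LXR-DKO, and lie between -0.0365 and 0.224 in Macrophage-depleted.

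Immediate early and handling genes were higher in Mertk-KO: 10 of 21 rose and 14 rose when adjusted over the list alone (camera adjusted p 1.13e-07; adjusted p = 0.530 with an estimated correlation), with a list median of 1.00 in Mertk-KO 1 and 0.87 in Mertk-KO 2. Lysosomal genes were higher, 3 of 22 rising and 6 when adjusted over the list alone, among them Ctsd and Lamp1 (adjusted p 0.00160; adjusted p = 0.530 with an estimated correlation). Immune lists differed between the Mertk-KO libraries. All 7 MHC class II genes rose when adjusted over the list alone and 0 over all genes tested (adjusted p 0.00402; adjusted p = 0.741 with an estimated correlation), with a median of 2.32 in Mertk-KO 2 and 0.31 in Mertk-KO 1. Of 23 type I interferon genes, Bst2 and Irf9 rose and 7 rose when adjusted over the list alone (adjusted p 5.23e-05; adjusted p = 0.741 with an estimated correlation), with a median of 1.53 in Mertk-KO 2 and -0.05 in Mertk-KO 1. The pan-macrophage list was higher (0 of 18 rose, adjusted p 0.00470; adjusted p = 0.741 with an estimated correlation), with a median of 0.92 in Mertk-KO 2 and 0.19 in Mertk-KO 1. Without Mertk-KO 2 these 3 lists had adjusted p of 0.561, 0.855 and 0.561.

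The unfolded protein and integrated stress response list was higher in Mertk-KO (2 of 23 rose and 7 when adjusted over the list alone, adjusted p 0.00470; adjusted p = 0.530 with an estimated correlation) and was lost without Mertk-KO 2 (0.0664). The oxidative stress and metal list was higher (4 of 25 rose and 8 when adjusted over the list alone, among them Gpx4 and Prdx5, adjusted p 0.00919; adjusted p = 0.530 with an estimated correlation) and was lost without Mertk-KO 1 (0.146) or WT 1 (0.0527). Among ion channels Kcnd2, Cacna2d1 and Kcnj3 fell, in a list that did not shift (adjusted p 0.133). The atrial list did not pass either (adjusted p 0.119), although 4 of its 7 genes fell when adjusted over the list alone. The atrial myosin light chain Myl7 ranged from 505 to 3242 normalised counts within WT and was at 203 and 22.6 in the Mertk-KO libraries.

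The comparison of LXR-DKO with WT asks what loss of both liver X receptors does to heart RNA. Among the genes named by the rule, which leaves out predicted gene models, the 3 with the largest fitted rises were on chromosome 7. Kcnj14, a potassium channel gene (45816460 to 45824782), was at 760 ± 18.0 normalised counts (SD, n = 3) against 12.6 ± 3.85 (n = 3) in WT (log2 fold change 5.85, SE 0.25, adjusted p 1.74e-07). The kallikrein gene Klk1b22 (44112673 to 44116922) had 0 reads in WT and 53.9 ± 6.38 normalised counts in LXR-DKO, at least 51.6-fold higher against a floor of 3 reads over the group. Gabrg3, a subunit of the GABA receptor, was at 63.1 ± 11.8 against 1.04 ± 0.0199, the latter from 3 reads in all. The processed pseudogenes Gm5900, on chromosome 7, and Gm10093, on chromosome 17, were chosen after their values were seen. They had the 2 largest fitted log2 fold changes of all genes higher in LXR-DKO (7.70, adjusted p 1.24e-05, and 6.52, adjusted p 0.000295), which depend on the pseudocount, since Gm5900 was at 0.0819 ± 0.142 normalised counts in WT and Gm10093 had 0 reads there. Gm10093 shares sequence with Hdac1, and the values of both pseudogenes are uncertain. Igsf23, Ush1c and Lrrc4b, on chromosome 7 too, and Abca4, on chromosome 3, rose by 1.86 to 2.67 on the log2 scale, and Pcna-ps2 was at 94.3 ± 36.4 against 2.96 ± 2.89.

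Besides Nr1h2 and Nr1h3, the transporter gene Slc6a17 fell (2.00 ± 0.870 against 87.3 ± 20.2 normalised counts; log2 fold change -4.89, SE 0.27, adjusted p 1.58e-06). Jmjd7, Tmem56 and Rsl1 fell as well, with log2 fold changes from -2.63 to -2.41. The netrin receptor gene Unc5a, with 2 estimated reads in LXR-DKO and 72 in WT, and Xlr3b, with 1.85 and 80.8, also fell. In all, 58 of 13884 genes changed in LXR-DKO, 30 higher and 28 lower, and 1601 had an unadjusted p below 0.05. The 7 changed genes on chromosome 3 all started between 107467543 and 135485611, and the 6 on chromosome 13 between 54949411 and 67173182. No targeted gene lies on either. The 9 on chromosome 2 started between 91184061 and 127704386. None of these 3 chromosomes passed (Fisher's exact test, one-sided, adjusted p 0.138, 0.117 and 0.148). Whether calls gather within these stretches was not tested. Of the 58, 20 (34.5%) lay on chromosome 7, which holds 7.90% of the genes tested (Fisher's exact test, one-sided, adjusted over the chromosomes, p 1.15e-07). The count was 37 without WT 1, 31 without WT 2, 36 without WT 3, 34 without LXR-DKO 2, 118 without Mertk-KO 1 and 116 without Mertk-KO 2. It was 593 with weights per library, 124 when only the 2 groups were fitted and 25 on the per-million scale. Among 14 genes named besides the receptors, 10 passed whichever library was left out; Jmjd7, Tmem56, Xlr3b and Igsf23 did not, with 10 of the 14 passing without LXR-DKO 1 or without WT 2. All 10 that were tested in the TPM table passed there, with Kcnj14 at 4.64, Klk1b22 at 3.67 and Slc6a17 at -1.92.

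**Figure D4:**
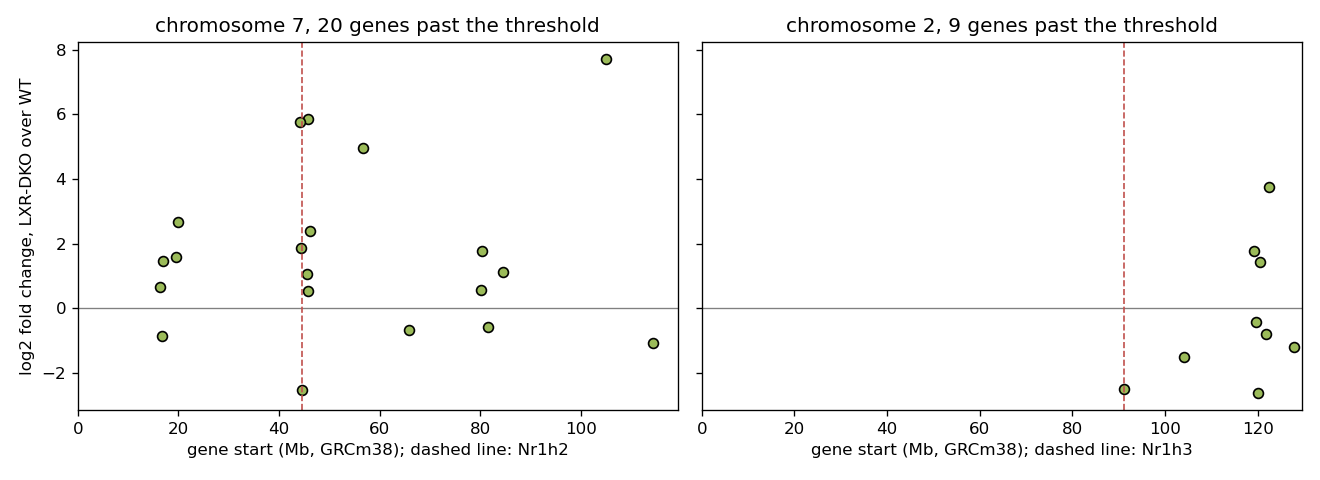
Log2 fold change, LXR-DKO minus WT (vertical axis), of the genes on chromosomes 7 and 2 that changed in LXR-DKO, by position in GRCm38 (horizontal axis). Chromosome 7 holds 20 of the 58 genes, with Kcnj14 at 5.85 and Nr1h2 at -2.52, and chromosome 2 holds 9. Changed genes of other chromosomes are not shown.

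Known LXR targets did not shift as a list in LXR-DKO hearts: of 19 tested, 13 were lower, and the camera adjusted p was 0.283. When adjusted over the list alone, Nr1h3 and Srebf1, a regulator of fatty acid synthesis (331 ± 42.7 against 496 ± 35.1), were lower, and Scd1 and Lpcat3 were higher. Nr1h3 is itself targeted in LXR-DKO, so its fall is given by the design and is not a response of a target. It is counted among the 13 lower and in the camera test, and the list was not tested without it. The nuclear-encoded respiratory chain list was higher, with 47 of 50 genes higher, 0 past the threshold in either count, a median of 0.17 and a camera adjusted p of 2.67e-08; the median was 0.0810 and the camera adjusted p 0.0132 once the trend with transcript length and GC was removed. The glycolysis list (adjusted p 0.00453, 1 of 21 when adjusted over the list alone) and the sarcomere list (0.0114, 1 of 17) were higher. The type I interferon list (0.0136, 0 of 23), the atrial list (0.0416, 0 of 7) and the fibroblast list (0.0416, 1 of 14) were lower. All 6 lists had adjusted p = 0.761 with an estimated correlation. Without LXR-DKO 3, 5 of them were lost, at 0.0628 for glycolysis and sarcomere, 0.0720 for interferon, 0.435 for atrial and 0.363 for fibroblast genes. The atrial list was also lost without WT 1 (0.274), LXR-DKO 1 (0.0783) or either Mertk-KO library (0.0557), and the fibroblast list without WT 2 (0.259) or either Mertk-KO library (0.0521). The median of the atrial list ranged from -1.30 to 1.29 within WT alone.

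Direct comparisons tested whether the perturbed groups differed from each other. Macrophage-depleted and Mertk-KO hearts differed in 2911 genes, 1607 higher and 1304 lower after depletion. Timd4 (1.66 ± 0.403 against 45.6 ± 26.9), Siglec1 (12.2 ± 18.7 against 77.4 ± 14.9), Mmp13 and Hspa1a were lower in Macrophage-depleted hearts, and Rxfp1, Hamp, Fgf12 and Muc16 were higher, Rxfp1 at least 12.8-fold and Hamp at least 7.33-fold by a floor of 3 reads over the group. The count was 1378 without Macrophage-depleted 2, 1640 without Macrophage-depleted 3 1366 (501 higher, 865 lower) after the trend with length and GC was removed, 1583 in the TPM table, 438 with weights per library and 146 when only the 2 groups were fitted. Of the 8 named genes 4 passed without Macrophage-depleted 2 and 4 without Macrophage-depleted 3, Muc16 was also lost without Macrophage-depleted 1, Hspa1a and Muc16 without Mertk-KO 1 and Fgf12 without Mertk-KO 2, and Timd4, Mmp13 and Rxfp1 passed whichever library was left out. Fgf12 was also lost in the TPM table (1.44 in place of 3.56 on the log2 scale).

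Macrophage-depleted and LXR-DKO hearts differed in 450 genes, 187 higher and 263 lower after depletion. Slc6a17, Unc5a, Xlr3b and Pde11a were higher in Macrophage-depleted hearts. Kcnj14, Klk1b22, Gabrg3 and the clock gene Arntl (18.2 ± 11.3 against 174 ± 21.0 normalised counts; log2 fold change -3.38, SE 0.54, adjusted p 0.00697) were lower. The count was 294 without WT 1, 280 without WT 2, 270 without WT 3, 194 without Macrophage-depleted 2, 188 without Macrophage-depleted 3, 154 without LXR-DKO 1, 135 without LXR-DKO 2 and 1229 without Mertk-KO 1 or without Mertk-KO 2. It was 217 in the TPM table and 2043 with weights per library. Of the 8 named genes, Xlr3b was lost without LXR-DKO 1 or Macrophage-depleted 2 and Pde11a without LXR-DKO 2. In the TPM table Slc6a17 was at 1.67 in place of 4.46, Kcnj14 at -4.53 in place of -5.78 and Arntl at -2.50 in place of -3.38 on the log2 scale.

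Mertk-KO and LXR-DKO hearts differed in 341 genes, 95 higher and 246 lower in Mertk-KO. Unc5a, Slc6a17, Xlr3b and Hspa1a were higher in Mertk-KO hearts and Kcnj14, Klk1b22, Gabrg3 and Rxfp1 lower. After the trend with length and GC was removed 222 were higher and 142 lower. The count was 138 without WT 1, 143 without WT 2 or WT 3, 179, 155 and 186 without Macrophage-depleted 1, 2 and 3, 2168 without Mertk-KO 2, and 72, 212 and 74 without LXR-DKO 1, 2 and 3. It was 82 in the TPM table, 19 with weights per library and 20 when only the 2 groups were fitted. Of the 8 named genes, 5 passed whichever library was left out. Hspa1a, at 2007 in Mertk-KO 1 and 105 in Mertk-KO 2, was lost without any 1 of the LXR-DKO libraries, Rxfp1 without LXR-DKO 1 or 2, and Xlr3b without LXR-DKO 1 or 3, Mertk-KO 1, Macrophage-depleted 1 or 2 or any 1 of the WT libraries. In the TPM table Hspa1a was lost (3.75 in place of 4.64) and Slc6a17 was at 1.66 in place of 4.33 on the log2 scale.

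Comparisons with the same WT libraries share their chance values, so the similarity of effects was set beside simulated unchanged groups. Across 13884 genes, the log2 fold changes of Mertk-KO and LXR-DKO correlated at 0.374, against 0.445 simulated, and the covariance exceeded the simulated one by 0.0345 (0.0645 against 0.0300, SD of the simulated value 0.00196). For Macrophage-depleted and Mertk-KO the correlation was 0.127 against 0.447 simulated and the covariance 0.0190 against 0.0302, a difference of -0.0112 (SD of the simulated value 0.00190). That correlation was 0.207 without WT 2, 0.201 without WT 3 and 0.0462 without Mertk-KO 1. For Macrophage-depleted and LXR-DKO the correlation was 0.233 against 0.497 and the covariance 0.0262 against 0.0301, a difference of -0.00384 (SD of the simulated value 0.00187). The covariance thus lay above the simulated one for Mertk-KO and LXR-DKO and below it for both pairs with Macrophage-depleted. The simulated value holds the part that shared controls give, as far as the simulated spread is right. It could not be checked on the libraries, since 3 WT libraries cannot be split into parts of at least 2. For Mertk-KO and LXR-DKO, part of the excess may come from the trend with transcript length, which ran the same way in both. Spearman's rho was -0.255 and -0.50 in the Mertk-KO libraries and -0.250, -0.374 and -0.142 in the LXR-DKO libraries. Genes higher in both comparisons numbered 8 for Mertk-KO and LXR-DKO, 4 for Macrophage-depleted and Mertk-KO and 4 for Macrophage-depleted and LXR-DKO, where independent lists would share 1.01, 0.372 and 0.0238. Genes lower in both numbered 2, 1 and 1, where independent lists would share 1.65, 1.30 and 0.0444, and 0, 2 and 1 went opposite ways. Values for independent lists leave out the shared WT libraries, so no shared effect is read from these overlaps. The 6 genes changed in all 3 comparisons, named after their values were seen, were Cd59a (lower in each), Gchfr, Capn3, Pcna-ps2 and Gm14085 (higher in each) and Klhdc8a (lower in Macrophage-depleted, higher in the others), and 4 of them, Cd59a, Gchfr, Gm14085 and Capn3, lie on chromosome 2 between 104095801 and 122528040. The targeted Nr1h3 (from 91184061), Mertk (from 128698956) and Siglec1 (from 131069220) lie on either side of this stretch. Chromosome 2 holds 7.99% of the genes tested. Its calls did not pass Fisher's exact test, one-sided (adjusted p 0.662, 0.132 and 0.148 for Macrophage-depleted, Mertk-KO and LXR-DKO against WT). Whether DNA kept around the targeted genes accounts for these genes was not tested.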

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

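The tests of distance to Nr1h2, of the LXR target list, of single Mertk-KO libraries and of Pcna with its pseudogene were chosen only after the results were seen, as were the genes named here outside the rule. Egln3, a prolyl hydroxylase of the oxygen response, differed between groups in the opposite direction: its log2 fold change against WT was -0.60 in Macrophage-depleted and 0.78 in Mertk-KO, a difference of -1.38 (limma adjusted p 0.000173). Klhdc8a did so as well, with a difference of -1.34 between Macrophage-depleted and Mertk-KO (limma adjusted p 0.000457) and -1.52 between Macrophage-depleted and LXR-DKO (limma adjusted p 2.16e-05). Of 545 genes tested in the TPM table alone, a signal outside the main measurement, 23 passed in Mertk-KO against WT (8 higher, 15 lower) and 7 in LXR-DKO against WT (4 higher, 3 lower), while 0 passed in Macrophage-depleted against WT (limma), where 36 had an unadjusted p below 0.05. All 7 in LXR-DKO and most of the 23 in Mertk-KO were annotated as pseudogenes. Their values are uncertain, since pseudogenes can share reads with other genes.

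Of the genes changed in LXR-DKO other than Nr1h2, 19 lay on chromosome 7, 15 higher and 4 lower. Removal of each library's trend with transcript length and GC left 17 of the 19 past the threshold, with a median absolute log2 fold change of 1.47 before and 1.42 after, which argues against that trend as the cause. DNA of another strain kept around the targeted Nr1h2 may account for some. Of the 19, 7 lay within 20 Mb of Nr1h2, as did 329 of the 1095 chromosome 7 genes tested other than Nr1h2 (Fisher's exact test, one-sided, p 0.335). A window this wide cannot show whether calls gather closer to Nr1h2 (44549616 to 44553951). Klk1b22, Lrrc4b, Bcat2, Rpl18, Kcnj14 and Ush1c lay between 44112673 and 46238503, and the rest of the 19 outside this stretch. Whether more calls lay in this stretch than its tested genes would give was not tested. The LXR target list (camera adjusted p 0.283) cannot decide about these calls, since only 1 of its members was tested on chromosome 7. Loss of LXR acting on its targets would not by itself gather calls on 1 chromosome. The 20 of 58 calls on chromosome 7 (Fisher's exact test, one-sided, adjusted p 1.15e-07) argue against it as the cause of this excess. It stays open for single genes. The sources used here do not give the strain of each group, so the cause of a single call cannot be told.

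The nuclear-encoded respiratory chain list was higher in Mertk-KO and LXR-DKO. A single Mertk-KO library is argued against, since the lower of their list medians was 0.26, above every WT library. The trend with transcript length and GC may account for part of the shift: once it was removed, the median went from 0.32 to 0.15 in Mertk-KO (interquartile range 0.16, camera adjusted p 8.60e-07, 5 genes past the threshold in place of 21) and from 0.17 to 0.0810 in LXR-DKO (interquartile range 0.15, camera adjusted p 0.0132). Before removal the list's call was lost in both groups with an estimated correlation, at adjusted p = 0.710 in Mertk-KO and adjusted p = 0.761 in LXR-DKO with an estimated correlation. The trend and a change of these genes with genotype cannot be told apart here, because the trend differs between the groups themselves and the list is made of short transcripts.

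Pcna-ps2 was higher in all 3 groups against WT. It shares 565 of its 751 words of 31 bases (75.2%) with Pcna, and Pcna was lower in each group, its highest value there being 397 normalised counts against 435 in the lowest WT library, which argues against transcription of Pcna-ps2 alone. The sum of both genes differed from WT by at most 0.12 on the log2 scale, in Mertk-KO, so reads shared between Pcna and Pcna-ps2 are a candidate explanation. Pcna lies on chromosome 2 (132249162 to 132253314), as do the targeted genes Siglec1 (131069220 to 131086765), Mertk (128698956 to 128802894) and Nr1h3 (91184061 to 91202834). Why the sharing would differ between WT and the other groups was not tested.

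With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave 33 genes for Macrophage-depleted against WT, 58 for LXR-DKO against WT and 450 for Macrophage-depleted against LXR-DKO, and the highest other split gave 0, 0 and 1; in each case 1 of the 10 splits, the real one, gave as many.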

How the results depend on the processing

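The voom, per-million, length and GC, and no-Mertk-KO alternatives were chosen after seeing the data. No targeted gene and no gene named by the size of its change turned direction under the alternatives run, but the nuclear-encoded respiratory chain list of Macrophage-depleted turned up without Macrophage-depleted 2 (camera adjusted p 0.917). With the length and GC trend removed the balance of higher and lower genes turned in Mertk-KO against WT (469 and 818 to 231 and 117), Macrophage-depleted against Mertk-KO (1607 and 1304 to 501 and 865) and Mertk-KO against LXR-DKO (95 and 246 to 222 and 142). Of 106 values for the targeted genes 16 were weaker and 3 stronger, of 1809 for named genes 360 were weaker, and of 165 counts of genes 57 were weaker and 20 stronger. Where a cause is not given by the alternative's own construction, the cause was not tested. A lone Mertk-KO library is assumed to vary like the other groups, and the lowest genes rest on a few reads.

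For Macrophage-depleted against WT (33 genes) the count was 17 with no minimum, 6 in the TPM table, 18 without trend, 219 with weights per library, 66 with only the 2 groups, 54 at a threshold of 0.1, 15 on the per-million scale and 84 without the Mertk-KO libraries; leaving out 1 library gave 3 to 84. For Mertk-KO against WT (1287) it was 597 with no minimum, 389 in the TPM table, 335 without trend, 12 with weights per library, 1 with only the 2 groups, 2625 at a threshold of 0.1 and 348 with the length and GC trend removed; leaving out 1 library gave 70 to 2399. For LXR-DKO against WT (58) it was 593 with weights per library, 124 with only the 2 groups, 25 on the per-million scale and 117 without the Mertk-KO libraries; leaving out 1 library gave 31 to 118.

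For Macrophage-depleted against Mertk-KO (2911) the count was 1583 in the TPM table, 438 with weights per library, 146 with only the 2 groups and 1366 with the length and GC trend removed; leaving out 1 library gave 1378 to 3237. For Macrophage-depleted against LXR-DKO (450) it was 278 with no minimum, 217 in the TPM table, 226 without trend, 2043 with weights per library, 1064 at a threshold of 0.1 and 1226 without the Mertk-KO libraries; leaving out 1 library gave 135 to 1229. For Mertk-KO against LXR-DKO (341) it was 150 with no minimum, 82 in the TPM table, 88 without trend, 19 with weights per library, 20 with only the 2 groups, 1112 at a threshold of 0.1 and 162 with voom; leaving out 1 library gave 72 to 2168.

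With the replicate number as a block the counts were 391 for Mertk-KO against WT, 119 for Mertk-KO against LXR-DKO, 22 for Macrophage-depleted against WT, 53 for LXR-DKO against WT, 2036 for Macrophage-depleted against Mertk-KO and 313 for Macrophage-depleted against LXR-DKO, and Mertk was at -0.78 (limma adjusted p 0.0606). The labels do not pair the libraries by number. Deviations of same-numbered libraries correlated at -0.0937 to 0.107 over 15 pairs, 2 of them over 0.1, and those of different numbers at -0.116 to 0.111 over 30. Deviations are taken from each group's own mean, so these correlations depend on each other and cannot exclude a shared litter or day.

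The log2 fold change of Siglec1 passed the threshold with weights per library (-3.87) and voom (-4.07). That of Mertk did not pass with no minimum (-0.71), in the TPM table (-0.52), with quantile scaling (-0.65), without trend (-0.71), with weights per library (-0.71), with only the 2 groups (-0.71), with voom (-0.71) or with the length and GC trend removed (-0.65), and that of Nr1h3 did not in the TPM table (-0.52). Leaving out 1 library gave -4.66 to -2.49 for Siglec1, -0.83 to -0.60 for Mertk, -2.53 to -2.45 for Nr1h3 and -2.57 to -2.46 for Nr1h2. Lists past the threshold numbered 12, 11 and 6 for Macrophage-depleted, Mertk-KO and LXR-DKO against WT, 0 in each with an estimated correlation, and 0, 6 and 0 with fry, and 3 for LXR-DKO in the TPM table; leaving out 1 library gave 10 to 16, 6 to 13 and 1 to 9.

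The correlation of fold changes between Macrophage-depleted and Mertk-KO (0.127) was 0.182 in the TPM table, 0.0287 with a minimum of 50 and 0.185 with the length and GC trend removed; leaving out 1 library gave 0.0462 to 0.207. Between Macrophage-depleted and LXR-DKO (0.233) it was 0.132 with a minimum of 50; leaving out 1 library gave 0.158 to 0.325. Between Mertk-KO and LXR-DKO (0.374) it was 0.457 in the TPM table, 0.428 with a minimum of 50 and 0.314 with the length and GC trend removed; leaving out 1 library gave 0.280 to 0.423.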

Other observations

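The clock genes Arntl and Per2 and the pseudogene pair of Hdac1 were chosen after their values were seen, and no explanation was tested. In hearts labelled Mertk-KO, Acta1, the skeletal muscle actin, rose (9213 ± 3480 against 3146 ± 1153 normalised counts in WT, log2 fold change 1.56), and Rcan1, an inhibitor of calcineurin, rose (1466 ± 257 against 910.2 ± 106), while Xirp2 fell (5147 ± 2252 against 8520 ± 491). The hypertrophy and wall stress list they belong to did not shift (camera adjusted p 0.817). The clock genes Nr1d2 and Per3 fell in Mertk-KO, in a list that did not shift there either (camera adjusted p 0.313).

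Arntl was at 200, 73.7 and 69.2 normalised counts in WT, 7.04, 29.7 and 18.0 in Macrophage-depleted, 92.9 and 331 in Mertk-KO and 167, 157 and 197 in LXR-DKO. Per2 was at 88.3, 193 and 203 in WT, 428, 407 and 509 in Macrophage-depleted, 182 and 25.9 in Mertk-KO and 71.3, 104 and 135 in LXR-DKO. The time of collection is not given in the sources used here.

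Gm10093, a processed pseudogene on chromosome 17 that shares 1218 of its 1414 words of 31 bases (86.1%) with Hdac1, had 0 reads in the 8 libraries of the other groups and 85.3, 135 and 64.9 normalised counts in the LXR-DKO libraries. In the TPM table it was at 0.297 in Macrophage-depleted 1, 0.123 in Macrophage-depleted 2 and 2.73, 3.89 and 2.24 in the LXR-DKO libraries. Hdac1 was at 171 ± 15.1 in LXR-DKO and 295 ± 13.1 in WT, and the sum of both genes at 266 ± 46.8 and 295 ± 13.1.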
